A study of Mus musculus with 8 samples.

How the data were processed

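RNA from costal chondrocytes of 8 mice, 4 WT and 4 Mir324-null, was sequenced, and 1 table of gene-level values for all 8 samples was used. The deposited values are TPM, 1 column per sample with no pooling. The authors call them length-scaled. Once repeated identifiers were counted once, each column summed to 1000000, so they were treated as TPM in which the authors had removed library size. The table has 52865 rows and 52325 gene identifiers; 273 identifiers were repeated on 813 rows with identical values and were counted once. With the repeats included, the column of null replicate 3 had the largest sum (1020436.2), so its deposited unit was entered as other; it too summed to 1000000 without them and was treated as TPM. Kallisto and DESeq2 are named, with no versions and no roles, per the submitters' processing notes. Those notes name the human build GRCh38, whereas the identifiers are mouse Ensembl genes, so the transcriptome used is not known; per the labels a low-input kit from NEB was used on total RNA, and strand use in counting and any selection of RNA are not given in the sources used here. Identifiers were matched to GENCODE M21 (GRCm38), which may not be the authors' annotation: 52220 matched. No other per-sample columns were present.

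The design assumed length-scaled counts and a count model, with limma-trend on log2(TPM + 1) as the fallback if the table held TPM. It held TPM, so the fallback was used. Genes with a TPM of at least 1 in 4 or more libraries were tested (13910) with limma 3.58.1 in R 4.3.3, with genotype as the only term, a trended prior variance and Benjamini-Hochberg adjustment at 0.05. A fold change is on the log2(TPM + 1) scale and understates the change of low genes. TPM is compositional: a shift in a few abundant genes moves all others. The median log2 fold change of all tested genes was -0.05, and 0.00269 after scaling by the median of ratios. TPM records no depth and none was estimated, so no interval for counting error is given. No pair of libraries had the same TPM at more than 0.769% of tested genes, and all 8 were kept as separate samples.

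Gene lists were fixed from textbook knowledge, 27 in all: cartilage matrix; chondrocyte transcription factors; hypertrophic chondrocyte; hedgehog signalling; osteoblast; osteoclast; macrophage and monocyte; neutrophil; lymphocyte; erythroid; endothelial; skeletal muscle; perichondrium, tendon and fibroblast; adipocyte; dissociation stress and immediate early; inflammatory NF-kappa-B response; interferon-stimulated; cell cycle and proliferation; mitochondrially encoded; matrix proteases and inhibitors; Wnt pathway; BMP and TGF-beta pathway; unfolded protein response; hypoxia and glycolysis; circadian clock; reported miR-324 targets; and the Mir324 chromosomal neighbourhood. Some genes belong to more than 1 list. The 25 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, which asks if a set moves on balance in a single direction. A list score is the mean log2(TPM + 1) of its tested members, compared between groups with an exact two-sided permutation test over 70 labelings, whose smallest p is 0.0286. After adjustment over the 27 lists the smallest p for a score was 0.771.

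Seed sites are 7-base matches to bases 2 to 8 of each mature form, sought in the longest annotated 3′ UTR. The mature sequences were located in the Mir324 hairpin of GRCm38. The difference of median log2 fold change was ranked among control sequences made of the same 7 bases with as many CpG pairs and at least 50 genes each.

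The rule for named genes was set before the data were examined: Mir324, Acadvl, Dlg4, Dvl2, Gli1 and Smo, with 1 further gene that is not reported here; the 10 genes with the largest change each way among those past the threshold with groups that do not overlap and a mean of at least 1, and, where fewer than 5 passed in a direction, the 5 with the smallest p in it; and 2 to 4 members with the smallest p of each list described, although for some lists that did not pass fewer are named. Predicted gene models, pseudogenes, Xist and Y-linked genes were counted and not picked.

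The procedures were tested on simulated data with the real genes' means and limma's moderated spreads (13910 genes, 4 against 4). In these data 67, 67 and 66 protein-coding genes were changed by 1.5, 2 and 4-fold. The changes were put in on the log2(TPM + 1) scale, so those of low genes were larger in TPM. The test recovered 1.49% of the 1.5-fold, 38.8% of the 2-fold and 83.3% of the 4-fold changes, with 5 false calls. Of 100 random lists of 20 genes, 2 had a camera p under 0.05. A seed effect of 0.1 log2 was recovered as 0.0977 (SD 0.0109 over 20 simulated draws). These simulations draw each gene independently, so they hold no correlation between genes.

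Alternatives were median-of-ratios scaling, a pseudocount of 0.1, no filter on low values, a mean TPM of at least 1, the replicate number as a block, the log ratio of Xist to Y-linked genes as a covariate, leaving out each library, a longer site of 8 bases, and 3′ UTRs of 200 to 3000 bases. Those added after seeing the data were protein-coding genes only, array quality weights, the first residual component, libraries with Xist above 1 TPM, removal of each library's smooth trend with transcript length, the excess over control sequences, pairs of list scores permuted within genotype, and camera's estimated correlation within each alternative. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1, numpy 2.4.6 and matplotlib 3.10.9 was used for sites, tables and figures.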

Results

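RNA was sequenced from chondrocytes freed by collagenase from the rib cages of 8 mice. Libraries were made from total RNA, and any selection of RNA is not given in the sources used here. The mice were 4 wild types (WT) and 4 animals lacking the microRNA gene Mir324 (Mir324-null), and each library came from a separate animal. The values are TPM (transcripts scaled to a fixed total per library), which keep no direct record of sequencing depth. Depth was not estimated, and no interval that needs it is given. Genes at 1 TPM or more numbered from 13229 in null replicate 3 to 14477 in null replicate 2. Col2a1, which encodes the main collagen of cartilage, stood at 39546 ± 4309 TPM in WT (SD, n = 4) and 37648 ± 5024 TPM in the null group (SD, n = 4). Acan, the aggrecan core protein, stood at 595 ± 32.1 TPM in WT and 672 ± 91.4 TPM in the null group (SD, n = 4 each).

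Null replicate 3 stood apart from the other 7 libraries. Its mean Spearman correlation with them over the tested genes was 0.864, against 0.895 for the next lowest library. Pseudogenes held 25.0% of its TPM and ribosomal protein genes 12.4%, while the highest values among the other libraries were 19.1% and 9.50%. The first principal component, with 27.1% of the variance, separated this library from the rest. Xist, the RNA made from the inactive X chromosome, was above 1 TPM in WT replicates 1, 3 and 4 and null replicates 1 and 2, and the Y-linked genes were expressed in WT replicate 2 and null replicates 3 and 4. The labels give no sex.

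**Figure D1:**
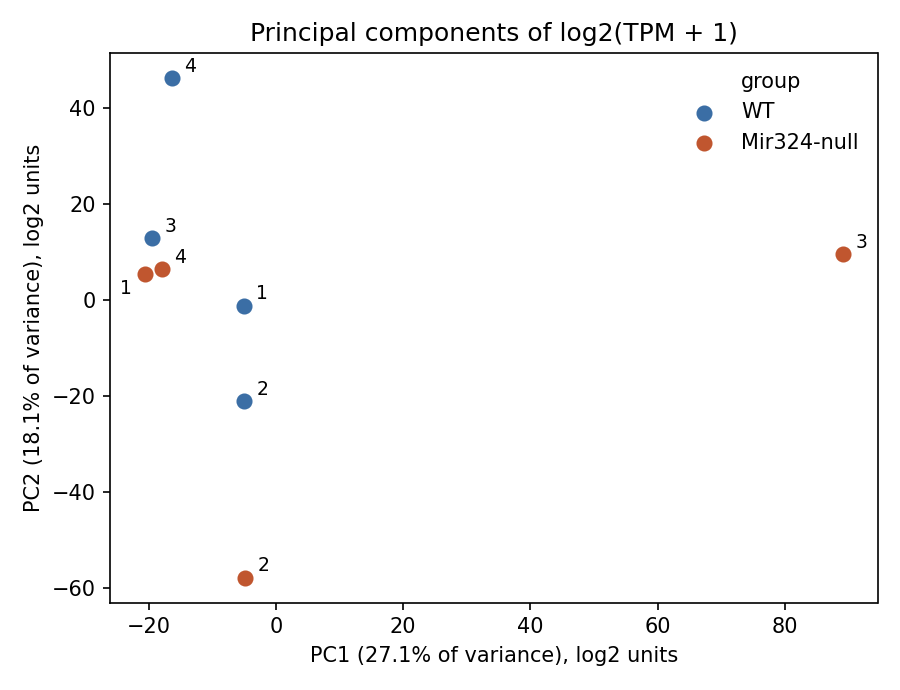
Principal components 1 and 2 of log2(TPM + 1) over the 13910 tested genes, with each point 1 library, coloured by group and numbered by replicate. Null replicate 3 lies alone at the right of the first axis (27.1% of the variance) while the other 7 libraries lie close together on it.

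The targeted gene came first as a check of the labels. Mir324 lies on chromosome 11 at 70012043 to 70012131 (GRCm38, plus strand), within the last exon and 3′ UTR of 2 annotated Dvl2 transcripts, at 70010877 to 70012301. The hairpin also lies inside the span of Acadvl, which is on the minus strand at 70010183 to 70015411. Mir324 was listed at 0 TPM in all 8 libraries, WT included, so it gave no check of genotype. The host and flanking genes were close between groups. Dvl2, a cytoplasmic transducer of Wnt signals, stood at 12.1 ± 1.03 TPM in WT and 11.4 ± 3.33 TPM in the null group (SD, n = 4 each), a log2 fold change of -0.13 with a 95% interval of -0.63 to 0.37. Acadvl, a mitochondrial fatty acid dehydrogenase, had a log2 fold change of 0.03 (95% interval -0.28 to 0.33). Dlg4, a synaptic scaffold gene, had -0.14 (95% interval -0.67 to 0.39). Of the 17 genes listed for this neighbourhood, 12 were tested and 0 passed limma's test at an adjusted p of 0.05, with 0 at an unadjusted p under 0.05. The list as a set gave 8 positive and 4 negative fold changes, a median of 0.02 and a camera adjusted p of 0.279; without null replicate 2 the median was 0.10 and the list passed with the preset correlation (camera adjusted p = 0.00964; adjusted p = 0.259 with an estimated correlation). Without null replicate 3, where Dvl2 stood at 6.79 TPM, Dvl2 and Dlg4 had 0.08 and 0.01. Whether strand was used in counting is not given in the sources used here, so reads from Dvl2 and Acadvl where they overlap cannot be told apart.

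**Figure D2:**
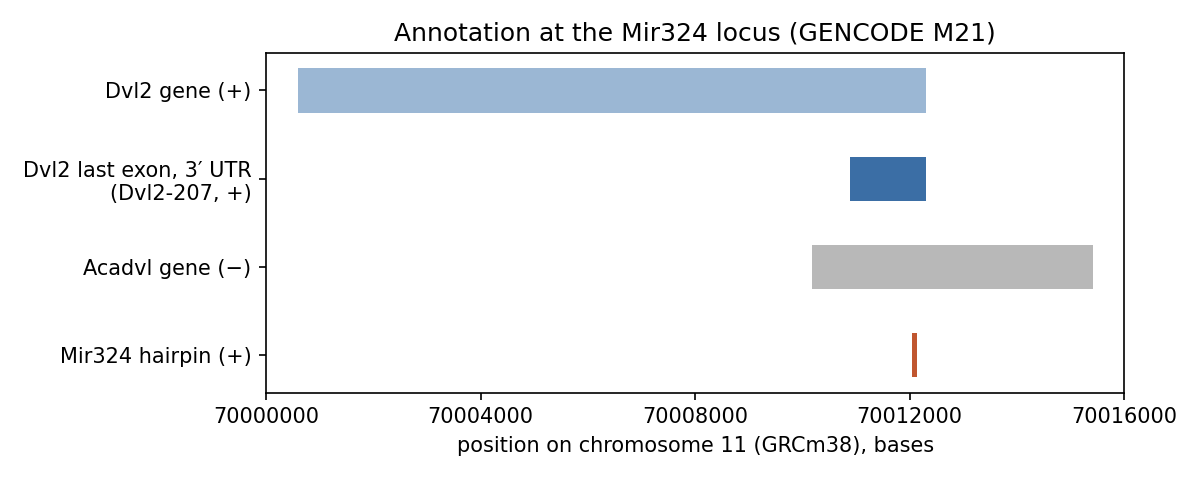
Annotated features at the Mir324 locus on chromosome 11 (GRCm38), with position in bases on the horizontal axis and 1 bar per feature, drawn to scale. The Mir324 hairpin, at 70012043 to 70012131, lies inside the last exon of Dvl2 and inside the Acadvl gene span.

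The question of which transcripts changed in chondrocytes without Mir324 was addressed over 13910 genes, of which 11397 are protein-coding. Few genes passed: 3 had an adjusted p under 0.05 in limma's trended test, 1 higher and 2 lower in the null group. The long non-coding RNA AC173345.1 was listed at 0 TPM in all 4 null libraries and at 1.56, 1.79, 2.18 and 2.13 TPM in WT replicates 1 to 4 (limma adjusted p = 0.00912). Scarna6, a small RNA that guides modification of spliceosomal RNAs in Cajal bodies, was listed at 0 TPM in all 4 null libraries and at 1.65, 3.78, 2.30 and 2.25 TPM in the WT libraries (limma adjusted p = 0.0332). Gm45666, an antisense gene model that falls outside the naming rule and was chosen after its values were seen, was listed at 0 TPM in all 4 WT libraries and at 1.25, 1.89, 1.46 and 1.72 TPM in the null libraries (limma adjusted p = 0.0138). Each of the 3 had an SD of 0 in the group listed at 0 TPM and passed the filter only through the other group. Their p-values therefore rest on the spread within 1 group and on limma's prior variance. No protein-coding gene was among the 3. The protein-coding gene 1110017D15Rik, outside the naming rule and chosen after its values were seen, had a limma adjusted p of 0.0542, at 0.176, 1.20, 0.306 and 0 TPM in WT replicates 1 to 4 and 6.45, 5.77, 6.20 and 4.17 TPM in the null libraries. It passed with protein-coding genes only, with array quality weights, without WT replicate 2 and in the libraries with Xist. None of the 3 passed without a filter on low values, with the ratio of Xist to Y-linked genes as a covariate, or after each library's trend with transcript length was removed, where 0 genes passed in each case, although their directions were the same. With the covariate, all 3 had a limma adjusted p of 0.0508. At an unadjusted p under 0.05 there were 577 genes, 248 higher and 329 lower, where 695.5 would be reached by chance.

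The remaining genes with the smallest p-values did not pass and are given as values. Mir24-2, the gene of a miR-24 precursor, stood at 33.9 ± 8.45 TPM in WT and 96.8 ± 24.7 TPM in the null group (SD, n = 4 each), a log2 fold change of 1.49 with a limma adjusted p of 0.278. Snord49b, a small nucleolar RNA, stood at 63.1 ± 16.6 and 132 ± 14.5 TPM (SD, n = 4 each; limma adjusted p = 0.662). Prok2, which encodes a secreted prokineticin, had a log2 fold change of 0.60, and Amhr2, the receptor for anti-Müllerian hormone, had 0.81. The long non-coding RNA AC091764.3 had 1.15, with WT replicate 3 listed at 0 TPM. On the lower side, Fut10, a fucosyltransferase gene, stood at 2.80 ± 0.35 TPM in WT and 1.41 ± 0.21 TPM in the null group (SD, n = 4 each). Gpsm2, which orients the mitotic spindle, stood at 33.5 ± 3.43 and 13.4 ± 7.05 TPM (SD, n = 4 each), a log2 fold change of -1.36. The mitochondrial lysine tRNA gene mt-Tk was listed at 0 TPM in null replicates 1, 3 and 4 and at 21.4 TPM in null replicate 2, against 40.5 to 82.8 TPM in WT. Values of such short genes repeat within a library. The mitochondrial tRNA gene mt-Tq was also at 21.4 TPM in null replicate 2. Mir24-2 and the small nuclear RNA gene Gm23851 were both at 33.4 TPM in WT replicate 1. Repeats of this kind can arise from a few reads each, so the sizes given for Mir24-2, Snord49b and mt-Tk are uncertain. Prok2, Amhr2, AC091764.3, Fut10, Gpsm2 and mt-Tk each had a limma adjusted p of 0.981. Gpsm2 passed without null replicate 1 (log2 fold change -1.66), and mt-Tk passed without null replicate 2.

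Precision bounds what these libraries could show. The 95% interval of the log2 fold change lay within 1 of no change for 11119 genes (79.9%), and within 0.58 (1.5-fold) for 5823 genes (41.9%). Both bounds are on the log2(TPM + 1) scale, so for low genes they allow larger changes in TPM. The 4 null values lay all above or all below the 4 WT values for 373 genes (2.68%), where chance gives 2.86%.

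Gene lists fixed beforehand moved in 4 cases out of 25 by camera with a preset correlation of 0.01, at an adjusted p under 0.05. No member of any list passed over all genes. Endothelial genes rose as a set by this test: all 11 tested members were higher in the null group, with a median log2 fold change of 0.76 (camera adjusted p = 6.27e-11). The adjusted p was 0.340 with an estimated correlation. Adjusted over the list alone, 4 members passed. They were Vwf, which encodes a clotting factor stored in endothelial cells, at 0.70 ± 0.32 TPM in WT and 1.98 ± 0.65 TPM in the null group; Pecam1, a junctional adhesion molecule, at 3.92 ± 2.26 and 7.90 ± 0.53 TPM; Robo4, at 0.87 ± 0.43 and 2.25 ± 1.0 TPM; and Cldn5, a tight junction claudin, at 1.95 ± 0.88 and 4.37 ± 1.88 TPM (SD, n = 4 each). The mean log2(TPM + 1) of the list was 1.80 ± 0.49 in WT and 2.45 ± 0.12 in the null group (SD, n = 4 each; exact permutation p = 0.0857, two-sided). WT replicate 3, at 2.42, lay within the range of the null libraries, and the median log2 fold change was 0.42 without WT replicate 1, where the list still passed. None of the 4 lists passed fry, where their smallest adjusted p was 0.429.

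The 13 listed protein-coding genes of the mitochondrial genome also rose as a set by camera with the preset correlation, with 11 of 13 higher, a median log2 fold change of 0.23 and an adjusted p of 6.95e-07. The adjusted p was 0.340 with an estimated correlation, and 0 members passed adjusted over the list alone. mt-Nd1, a subunit of respiratory complex I, stood at 837 ± 79.5 TPM in WT and 1077 ± 150 TPM in the null group (SD, n = 4 each). mt-Nd4 had a log2 fold change of 0.30 and mt-Cytb, of complex III, had 0.30. The list score of WT replicate 4, 10.31, lay within the range of the null libraries, 10.29 to 10.37.

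Immediate early and dissociation stress genes fell as a set by camera with the preset correlation: 18 of 19 were lower in the null group, with a median log2 fold change of -0.38 and an adjusted p of 1.30e-06. The adjusted p was 0.523 with an estimated correlation. Adjusted over the list alone, 2 members passed, the heat shock protein genes Hspa1a and Hspa1b. Hspa1a stood at 1386 ± 170 TPM in WT and 789 ± 194 TPM in the null group, and Hspa1b at 2324 ± 338 and 1402 ± 319 TPM (SD, n = 4 each). These near-identical paralogs share reads, so their separate values are uncertain. Btg2, an antiproliferative immediate early gene, had a log2 fold change of -0.65. Ier3 was the exception, at 0.47. Null replicates 1 and 4 had list scores of 8.96, within the WT range, while null replicates 2 and 3 were at 8.38 and 8.23. With array quality weights the median was -0.12, and the list still passed with the preset correlation.

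The unfolded protein response list, chaperones and stress factors of the endoplasmic reticulum, fell as a set by camera with the preset correlation, with 14 of 16 members lower, a median log2 fold change of -0.27 and an adjusted p of 0.00102. The adjusted p was 0.523 with an estimated correlation, and 0 members passed adjusted over the list alone. Creld2 stood at 29.9 ± 3.18 TPM in WT and 21.9 ± 3.01 TPM in the null group (SD, n = 4 each). Sdf2l1 had a log2 fold change of -0.48 and Manf, a secreted factor of the endoplasmic reticulum, had -0.38. The list score of null replicate 1, 7.83, lay within the WT range, 7.76 to 7.93. Without null replicate 3, which had the lowest score, the median was -0.12 and the list still passed with the preset correlation.

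**Figure D3:**
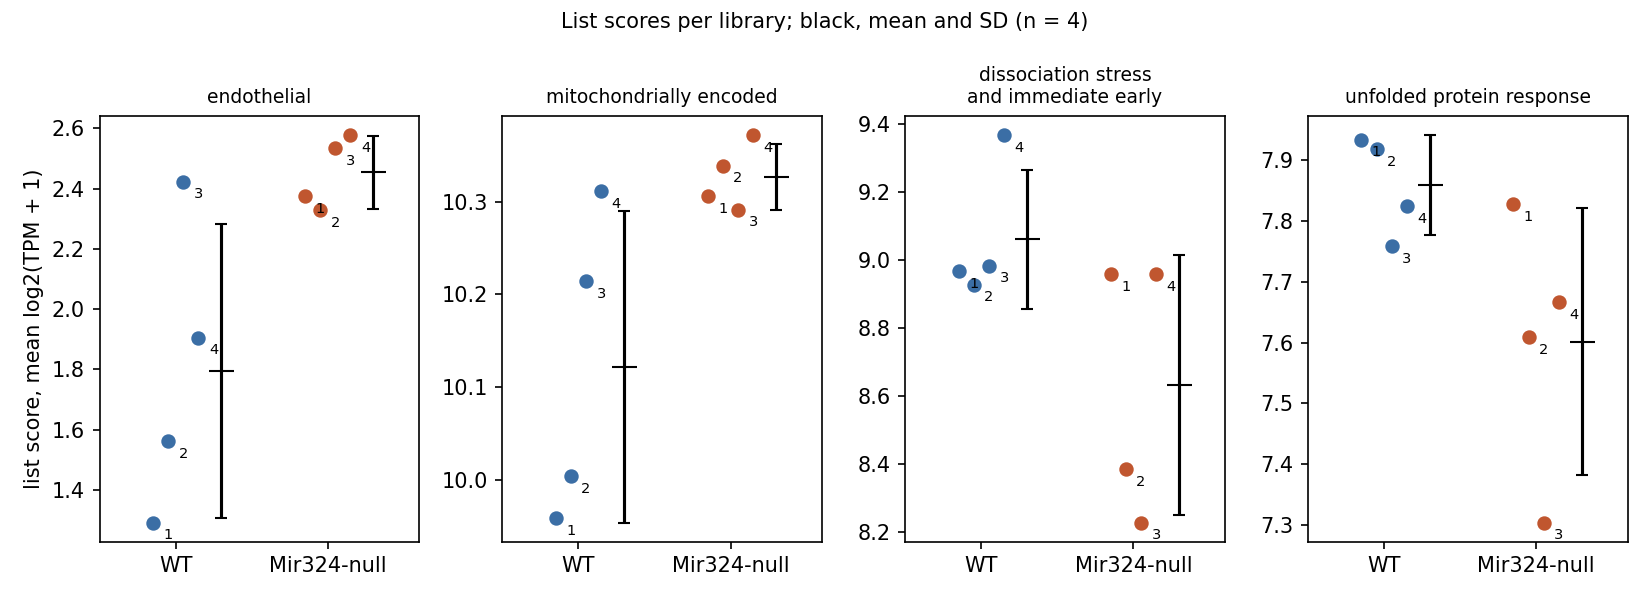
Score of each of 4 gene lists per library, as the mean log2(TPM + 1) of the tested members (vertical axis, which does not start at 0), with WT at the left and Mir324-null at the right of each panel. Coloured points are single libraries numbered by replicate, and black marks are the mean and SD (n = 4); the endothelial score of WT replicate 3 (2.42) lies among those of the null libraries.

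Chondrocyte gene lists did not pass as sets in the chosen test. Of the cartilage matrix list, 9 of 21 members were higher and 12 lower, with a median log2 fold change of -0.04 and a camera adjusted p of 0.715, in the upward direction although the median was negative. Prg4, the lubricin gene, stood at 34.3 ± 6.73 TPM in WT and 43.0 ± 2.46 TPM in the null group, and Matn3 at 276 ± 34.5 and 220 ± 54.6 TPM (SD, n = 4 each). All 10 tested chondrocyte transcription factors had negative fold changes, with a median of -0.18 and a camera adjusted p of 0.137. Sox9, the principal chondrocyte factor, stood at 153 ± 6.44 TPM in WT and 134 ± 4.65 TPM in the null group, and Sox6 at 81.1 ± 2.36 and 64.5 ± 20.8 TPM (SD, n = 4 each). The score of this list in null replicate 3, 3.33, lay below those of the other 7 libraries, which were 4.02 to 4.23. Hypertrophic chondrocyte genes gave 10 negative and 3 positive values (median -0.26, camera adjusted p = 0.185), among them Mmp13, a collagenase, with a log2 fold change of -0.48, and Spp1, the osteopontin gene, with -0.27. The hedgehog signalling list gave 8 negative and 3 positive values (median -0.15, camera adjusted p = 0.314). Gli1, a transcription factor and readout of hedgehog signalling, stood at 7.81 ± 1.79 TPM in WT and 4.97 ± 1.93 TPM in the null group (SD, n = 4 each), a log2 fold change of -0.61 with a 95% interval of -1.25 to 0.03 and a limma adjusted p of 0.981. Smo, the signal transducer of the pathway, had -0.26 with a 95% interval of -0.71 to 0.20. Much of this rested on null replicate 3: without it the medians were 0.00 for the transcription factors, -0.05 for the hypertrophic list and 0.02 for the hedgehog list, and Gli1 and Smo had -0.36 and -0.13. The transcription factor list passed camera with no filter on low values (adjusted p = 0.0235) and with the residual component (adjusted p = 0.0215), and the hypertrophic list passed with no filter (adjusted p = 0.0191), without WT replicate 2 (adjusted p = 0.0142) and in the libraries with Xist (adjusted p = 0.0496). These calls used the preset correlation, and for them the smallest adjusted p was 0.429 with an estimated correlation.

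The loss of a microRNA poses the question of whether transcripts with its binding sites are higher. Sites were matched in the longest annotated 3′ UTR of 11295 tested genes. For miR-324-5p, whose mature sequence maps to 70012060 to 70012082 of chromosome 11 (GRCm38), 951 genes held the site GGGATGC. Their median log2 fold change differed from that of the other genes by -0.0092, and camera gave an adjusted p of 0.729. For miR-324-3p, at 70012095 to 70012114, 1774 genes held GGCAGTG, with a difference of -0.0294 (camera adjusted p = 0.568). For a shorter 3p form, at 70012097 to 70012116, 1766 genes held GGGGCAG, with a difference of -0.0184 (camera adjusted p = 0.729). All 3 differences turned positive without null replicate 3, at 0.0287, 0.0130 and 0.0265, and 0 genes with a site passed the threshold. The medians of the control sequences turned positive there too, at 0.0179, 0.0179 and 0.0227. The sites exceeded these medians by 0.0108, -0.0049 and 0.0037, so the change of sign was largely shared with the controls. Genes named as miR-324 targets in earlier work gave 7 negative and 2 positive values of 9 tested (median -0.12, camera adjusted p = 0.329), among them Smad4, the shared partner of receptor-activated Smads, with -0.19. Without null replicate 3 that median was -0.01.

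Lists of skeletal lineages and of tissue adjoining cartilage did not pass in the chosen test. Osteoblast genes gave 7 negative and 3 positive values (median -0.20, camera adjusted p = 0.715), and osteoclast genes gave 3 of each (median -0.07, camera adjusted p = 0.832). Mmp9, a gelatinase of osteoclasts, had a log2 fold change of -0.51. The perichondrium, tendon and fibroblast list gave 9 positive and 7 negative values (median 0.05, camera adjusted p = 0.279), with Dpt, an extracellular matrix protein gene, at 0.65 and Thbs4 at 0.78. All 5 erythroid genes were positive (median 0.43, camera adjusted p = 0.185), including the near-identical globin genes Hba-a1 and Hba-a2, whose separate values are uncertain. All 3 neutrophil genes (median 0.34, camera adjusted p = 0.130) and all 4 adipocyte genes (median 0.17, camera adjusted p = 0.135) were positive. The 3 skeletal muscle genes gave a median of -0.48 (camera adjusted p = 0.628). Macrophage and lymphocyte lists had 2 tested members each, too few for a set test. Cd14, a coreceptor for bacterial lipopolysaccharide, stood at 33.5 ± 6.40 TPM in WT and 49.3 ± 8.73 TPM in the null group (SD, n = 4 each) and was the 1 of 2 macrophage members to pass adjusted over the list alone. The lymphocyte members gave 1 positive and 1 negative value. Several of these lists turned on single libraries. Without WT replicate 3 camera passed the erythroid list (median 0.91, adjusted p = 0.00566), the perichondrium list (median 0.35, adjusted p = 0.00787) and the adipocyte list (adjusted p = 0.0251), while without WT replicate 2 the erythroid and perichondrium medians were 0.08 and -0.16. The perichondrium list also passed without WT replicate 4 (adjusted p = 0.0203), the erythroid list with the covariate of sex-linked genes (adjusted p = 0.0300), the neutrophil list with no filter (adjusted p = 0.0124) and without WT replicate 1 (adjusted p = 0.0431) or null replicate 2 (adjusted p = 0.0170), and the muscle list in the libraries with Xist (adjusted p = 0.0496). These calls used the preset correlation, and the smallest adjusted p was 0.259 with an estimated correlation. The osteoblast median was 0.07 without null replicate 3, and the osteoclast median was 0.17 after median-of-ratios scaling.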

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

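The tests of a common scaling factor, of the length trend as the whole cause, of low expression, of the share of splits for genes and lists, of null replicate 3 as the cause of the list calls and of correlation within lists were chosen after the result was seen. Of 105 checks for a library far from the other 3 of its group, 9 passed the critical value. The check divides the gap to the nearest library by the range of the group, and chance passes about 1 group in 20.

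Null replicate 3 was set apart in its share of TPM from pseudogenes (25.0%, gap over range 0.8768) and from ribosomal protein genes (12.4%, 0.8985). It was likewise far below the rest in the score of chondrocyte transcription factors (3.33, 0.8326) and lowest in Fut10 (1.09 TPM, 0.8359). A common factor from a few abundant genes would leave ranks alone, and so as the whole cause is argued against by its mean Spearman correlation with the other libraries, 0.8645 against 0.8949 for the next lowest. Its deviations from the other null libraries correlated with transcript length across 11397 protein-coding genes (rho = -0.4792), more than in any other library (0.3588 in size, in null replicate 2, whose reference includes null replicate 3). A length trend is therefore present. With each library's trend removed the mean correlation was 0.8716 against 0.8919 for the next lowest, so the trend as fitted was not the whole cause. The fit used the longest annotated transcript of protein-coding genes and was carried over to other genes. It therefore cannot exclude length of the transcripts in fact expressed as the whole cause. The correlation with GC content was 0.1996, against 0.2048 in size in null replicate 2 and 0.1927 in WT replicate 4. By the rule set beforehand, a value below that of another library counted against GC bias. A margin that was not in that rule was applied to a gap this small, so GC bias is left open. A difference between mice is open too, since genotype does not account for a single library.

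The 3 genes past the threshold are a second pattern. Of the 35 splits of the 8 libraries into groups of 4, 30 gave as many genes (real value 3, highest other 18), so chance cannot be excluded. The split with 18, the highest of the others, put null replicates 2 and 3 with WT replicates 1 and 2. A count several times the real one may reflect a structure of the samples. Those libraries had the lowest erythroid scores (3.41 to 5.16, against 5.38 to 6.24 in the rest). Their perichondrium scores were also the lowest (4.66 to 5.46, against 5.75 to 5.97), while endothelial scores overlapped. These scores were compared after the split was known, and whether they account for the 18 genes was not tested. All 3 genes lay at or below the 0.561 percentile of mean expression, but values of 0 in a whole group and the filter fix a low mean, so this leaves values near the detection limit open. The 3 genes lie on chromosomes 1, 8 and 13, which argues against a segment of another strain around Mir324 as their local source. Of the 266 genes within 10 Mb of Mir324, 3.383% had an unadjusted p under 0.05, against 4.15% of the other genes (Fisher's exact p = 0.642, two-sided). This share cannot exclude a segment that alters few genes. Snord49b, at 62603079 on chromosome 11, lies in that window and had the smallest adjusted p there (limma adjusted p = 0.662). An effect of genotype on the 3 genes remains open.

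The 4 lists past the threshold with the preset correlation are a further pattern. Of the 35 splits, 19 gave as many lists (real value 4, highest other 13), so chance cannot be excluded. As the sole source of these calls, null replicate 3 is argued against, since all 4 lists passed in the same direction without that library. This check used the preset correlation too, so it does not separate the shifts from chance. Without that library the smallest camera adjusted p of the 4 lists was 0.720 with an estimated correlation. Correlation among the genes of a list, which makes the preset value too small, fits, as 0 of the 4 passed with an estimated correlation. Genotype, and the amount of vessel or the handling of each rib cage, stay open and cannot be told apart by these 8 libraries.

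The other checks past the critical value are given as values. The Col2a1 share of TPM in WT was lowest in replicate 2, at 3.31% (gap over range 0.8874). The stress and immediate early score in WT was highest in replicate 4, at 9.37 (0.874). Gli1 in WT was highest in replicate 4, at 10.5 TPM (0.8325). Gpsm2 in the null group was highest in replicate 1, at 24.0 TPM (0.8709). In the null group mt-Tk was above 0 TPM in replicate 2 alone, at 21.4 TPM (1.0).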

How the results depend on the processing

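The length trend, protein-coding genes, array weights, residual component, Xist and control-sequence alternatives, and the estimated correlation within alternatives, were chosen after seeing the data. The count of 3 genes became 5 with a pseudocount of 0.1, and 0 with no filter, with a mean TPM of at least 1, with the replicate block, with the sex-gene covariate and with the length trend removed. AC173345.1 and Gm45666 lay below the mean of 1 TPM, so that filter left them untested. The count was 1 for protein-coding genes only, which left out all 3 genes. It was 16 in the 5 libraries with Xist above 1 TPM, with 0 of the 3 genes among the 16. Leaving out 1 library gave 2 to 7 genes: 7 without WT replicate 1 or 2, 6 without null replicate 1, 5 without null replicate 2 and 2 without null replicate 3, where AC173345.1 was the 1 gene shared. The 4 lists became 7 with no filter, 8 in the Xist-positive libraries, and 0 with camera's estimated correlation or with fry; leaving out 1 library gave 4 to 7, with 7 without WT replicate 2 or 3. The cause was not tested. The 4 lists themselves passed with the preset correlation in the same direction under all 19 alternatives of the fit, and in none of them with an estimated correlation (smallest adjusted p 0.0674). The replicate block left 4 lists. The correlations of same-numbered samples were -0.04, 0.11, -0.05 and 0.11, and those of differently numbered samples ran from -0.13 to 0.11. So few values cannot settle whether same-numbered samples share more than a number. Named genes gave 314 alternative values: 285 on the same side of the threshold, 27 no longer past it, 2 newly past it and 0 reversed; 8 changed sign with no call in either fit. Lists gave 455 of 475 on the same side and 20 newly past, 0 of them with an estimated correlation. The seed differences passed nowhere, with ranges of -0.0391 to 0.0510 (5p), -0.0491 to 0.0268 (3p) and -0.0348 to 0.0283 (shorter form), or leaving out 1 library -0.0391 to 0.0287, -0.0491 to 0.0130 and -0.0348 to 0.0265, and changed sign in 6, 3 and 3 of 21 alternatives. Not run were library totals only (TPM is that already), DESeq2 and svaseq (which need counts), and limma on log2(CPM + 1), which on columns already scaled to 1000000 gives the same values as log2(TPM + 1). Depth is not recorded in TPM and was not estimated, so what it limits was not measured. Values shared between short genes may reflect few reads for some of them.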

Other observations

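The tests of the score pairs and of the excess over control sequences were chosen after the result was seen.

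Signalling and stress lists not described so far did not pass. The Wnt pathway list gave 10 negative and 8 positive values (median log2 fold change -0.06, camera adjusted p = 0.682). Sfrp5, a secreted Wnt antagonist, had the smallest p in it, at 5.63 ± 1.39 TPM in WT and 2.64 ± 0.81 TPM in the null group (SD, n = 4 each), with 4 of 4 null values below the WT values and 0 members passing adjusted over the list alone. The BMP and TGF-beta list gave 17 negative and 7 positive values (median -0.13, camera adjusted p = 0.924), with Chrdl2, a BMP antagonist, at 0.44 and Gdf5, a joint-forming growth factor, at 0.37. Matrix proteases and inhibitors gave 7 negative and 6 positive values (median -0.08, camera adjusted p = 0.682), with Adam17, a membrane sheddase, at -0.38. The inflammatory list gave 8 negative and 5 positive values (median -0.06, camera adjusted p = 0.788), among them Tnf at -0.52 and Tnfaip3, a brake on NF-kappa-B, at -0.77. Interferon-stimulated genes gave 7 negative and 1 positive value (median -0.20, camera adjusted p = 0.185), with Isg15 at -0.32. Hypoxia and glycolysis genes gave 12 negative and 3 positive values (median -0.17, camera adjusted p = 0.211), while Hk2, a hexokinase, had 0.29. Cell cycle genes gave 12 negative and 7 positive values (median -0.10, camera adjusted p = 0.832), with Bub1, a spindle checkpoint kinase, at -0.73. Clock genes gave 11 negative and 4 positive values (median -0.09, camera adjusted p = 0.788), with Ciart, a clock repressor, at 0.28 and Bhlhe41 at -0.62. The cell cycle list passed camera without WT replicate 2 (median -0.31, adjusted p = 0.000363) and in the libraries with Xist (median -0.28, adjusted p = 0.000115), and its median was 0.04 without null replicate 2. The hypoxia list passed without WT replicate 2 (adjusted p = 0.0167) and with array weights (adjusted p = 0.0444), and the inflammatory list in the libraries with Xist (adjusted p = 0.0496). These calls used the preset correlation, and the smallest adjusted p was 0.429 with an estimated correlation. Without null replicate 3 the Wnt, BMP and TGF-beta, clock, hypoxia and interferon medians were 0.04, 0.07, 0.09, -0.09 and -0.11.

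Transcripts with miR-324 sites gave no sign of release that these libraries could separate from chance. The prediction written beforehand was a difference above 95% of control sequences, against a difference of 0 or lower. The 3p site lay above 7.95% of 88 controls and the shorter form above 18.2% of 11. The 5p site lay above 98.9% of 88 controls, but its difference was itself negative, as were those of all the controls, so it met both values set beforehand and decides nothing. The controls ran from -0.0387 to -0.0079. All 3 differences met the value set against release, but within the spread over splits: 31 of the 35 splits gave a 5p difference as large in size (real value -0.0092, highest other 0.0713), 29 a 3p difference (-0.0294, 0.0685) and 33 a shorter-form difference (-0.0184, 0.0674). The excess of the 5p site over the control median was 0.0102, and 14 of 35 splits gave an excess as large in size (highest other 0.0226 in size, a negative excess), so chance cannot be excluded. Without null replicate 2 the excess was -0.0003. The test by splits of the 3 differences was set beforehand, whereas the rule that a difference had to exceed its SD over the splits to count against release was set after the values were seen.

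The scores of 2 lists for tissue next to cartilage, erythroid and perichondrium, varied together across mice. Among 28 pairs of 8 lists, each without shared genes, 5 had an unadjusted permutation p under 0.05 for r and 2 passed after adjustment. The erythroid and perichondrium scores had Pearson r = 0.9683 over 8 libraries (permutation p = 4.96e-05, adjusted 0.00139) and Spearman rho = 0.976 (permutation p = 0.000397, adjusted 0.0111), and r was 0.922 without the 2 libraries farthest from the median. Centred on each genotype and permuted within it (576 orderings), this pair had r = 0.969 (permutation p = 0.00174, adjusted 0.0486), the 1 pair of 28 to pass that test. Osteoblast and skeletal muscle scores had r = 0.848 (permutation p = 0.00248, adjusted 0.0347) with rho = 0.762 (permutation p = 0.0368, adjusted 0.257), the muscle list having 3 genes, and within genotype an adjusted permutation p of 0.271. The osteoblast and perichondrium scores, the pair first noticed, had r = 0.7758 (permutation p = 0.0240, adjusted 0.140) and rho = 0.857 (permutation p = 0.0107, adjusted 0.144), which leaves that pair open. A candidate explanation for the erythroid and perichondrium pair is that the amount of perichondrium and blood released with the cartilage may differ between rib cages.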
